A study of Mus musculus with 7 samples.

How the data were processed

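Treg cells sorted as CD4+ YFP+ from the spleen and lymph nodes of mouse chimeras were profiled on 7 single-colour arrays, 3 from KO and 4 from Het samples. Per the labels' protocols, total RNA was extracted with a column kit for small samples, amplified and converted to biotin-labelled cDNA with the NuGEN WTA Pico and Encore Biotin kits. Amplification from so little RNA can widen the spread between samples. Per the submitters' processing notes, the authors made the deposited log2 values with RMA in Affymetrix Expression Console 1.1. RMA corrects the background, equalises the distributions of the probe intensities and summarises the probes of each set on the log2 scale, so a change that affected most genes one way would be reduced. The array design, its probe sequences and a genome build are not given in the sources used here, and no coordinates are printed. Both deposited tables hold the same values, and 1 of them pairs probe sets with gene symbols.

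Groups were taken from the genotype in the sample labels, and replicates were numbered in order of deposit, so equal numbers do not pair samples. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. No scan date, slide or batch is given in the sources used here.

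Of 28846 probe sets, 22203 carried 1 gene symbol and 6643 none, and 0 carried several. The named sets represent 21902 genes, of which 203 had several probe sets. The probe set with the highest mean over the 7 arrays stood for the gene. Of the symbols, 20305 (92.7%) are current in the RefSeq gene table of GRCm38.p6, and 6 list members were matched through synonyms in it. Genes were kept where at least 3 arrays lay above that array's 95th percentile of the 1117 olfactory receptor probe sets, genes that a T cell is taken not to express. This kept 13083 genes and left out 8819. A gene below this floor on every array of a group has only a bound there: the mean of the brighter group was set against the dimmer group's mean of the higher of its value and the floor on each array, and is printed as at least that fold. Changes are KO minus Het on the log2 scale. Folds are 2 to the power of the change and are compressed for dim genes by the array background.

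Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. The smallest exact two-sided permutation p that 3 against 4 arrays allow is 0.0286. KO against Het data were simulated for 13083 genes with their real means and limma's moderated spreads. The noise was normal, equal in both groups and independent between genes, unlike real arrays, so the rates are those of limma's own model. Of 50 genes changed by 0.5 on the log2 scale 36% were recovered, 98% of 50 changed by 1, and 100% of those changed by 1.5 or 2. In that simulation, 12 of 179 calls were genes that had not been changed. Gene lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists that had at least 2 measured members. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the list mean of each array. With the preset correlation 4 lists were called higher and 9 lower. With an estimated correlation none of these 13 calls held (0 at the threshold, lowest adjusted p = 0.0674, 5 lists at an unadjusted p under 0.05). Fry, which asks only whether the genes of a list move one way on balance, called 12 lists. The exact test called 0 after adjustment, with 10 lists at the smallest p the splits allow.

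The tests, the 24 gene lists, the naming rule and the other settings listed below were chosen before the data were examined. The lists come from textbook knowledge, and the result of 1 of them is left out of the text. The others are effector, resting or central and core Treg genes, T cell receptor response, cell cycle, glycolysis, mTORC1 and amino acid response, cholesterol and mevalonate synthesis, oxidative phosphorylation, prenylation enzymes, homing, interferon response, helper T cell cytokines, apoptosis, heat shock, ribosomal proteins, T cell identity, and markers of B, plasma, myeloid, CD8 T and NK, erythroid and platelet, and conventional CD4 T cells. Named genes are Pggt1b, the 10 largest rises and 10 largest falls among called genes whose KO arrays all lie outside the Het range, the 2 members of each list with the smallest p, and 17 genes of Treg biology and prenylation. Some of these genes are left out of the text. Predicted genes, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out of the names of the largest changes, not of the counts. Other list members were named as examples after their values had been seen.

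The other settings were centring each array on its median, quantile normalization, no filter and a stricter filter, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, the olfactory background level as a covariate, each array left out in turn, other thresholds, and other list tests. A myeloid covariate, macrophage, dendritic cell, neutrophil, liver and salivary gland lists, and gene ontology terms were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.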

Results

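Gene expression was measured in regulatory T (Treg) cells, the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses. CD4+ YFP+ cells were sorted from the spleen and lymph nodes (abbreviated pLN in the labels) of mouse chimeras in which Cre is expressed with Foxp3. Pggt1b encodes the beta subunit of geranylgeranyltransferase type I, an enzyme that attaches a geranylgeranyl lipid to proteins. The 3 KO samples came from chimeras with Pggt1b floxed on both alleles, and the 4 Het samples from chimeras with 1 floxed and 1 wild-type allele. Each sample was 1 array with 28846 probe sets, and the number of arrays limits the precision. The 95th percentile of the olfactory receptor probe sets, used as the floor of each array, lay between 5.48 and 5.77 on the log2 scale. Across the 13083 genes above this floor, arrays of the same genotype correlated at 0.971 to 0.987 and arrays of different genotypes at 0.942 to 0.964. The first principal component held 46.0% of the variance and separated the genotypes.

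The comparison of KO with Het cells asks how the Treg transcriptome differs with both Pggt1b alleles floxed against 1. Effector Treg cells are the subject of the series. How far geranylgeranylation by this enzyme was lost was not measured. Of 48 measured effector Treg genes, 30 fell in KO cells (camera adjusted p = 7.51e-24 with a preset correlation, and adjusted p = 0.0674 with an estimated correlation). Among them the IL-33 receptor Il1rl1 fell 12.6-fold, the inhibitory receptor Tigit 8.70-fold and the integrin Itgae 4.74-fold. Il1rl1 was above the floor in 1 of 3 KO arrays and Tigit in 2 of 3, so their folds rest in part on values below it. Of 36 measured resting or central Treg genes, 8 rose and 28 did not pass, at a median log2 change of 0.28 (camera adjusted p = 0.126 with an estimated correlation). The rises were smaller, such as 2.30-fold for Ly6c1 and 1.63-fold for Klf2. Foxp3 differed by 0.06 ± 0.12 (SE) on the log2 scale, with an adjusted p of 0.836. Of 21 myeloid markers, 16 rose in the same KO arrays (adjusted p = 0.163 with an estimated correlation), among them Csf1r, the receptor for the macrophage growth factor CSF1, by 8.22-fold (above the floor in 2 of 4 Het arrays). Genes for ribosomal proteins and for oxidative phosphorylation were slightly lower as groups with the preset correlation (adjusted p = 0.292 and 0.542 with an estimated correlation).

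The Pggt1b probe set (TC1800001295.mm.2) read 6.59, 6.62 and 6.59 in KO samples 1 to 3 and 7.09, 7.11, 6.71 and 6.97 in Het samples 1 to 4. All 3 KO values lay below all 4 Het values, at a log2 difference of -0.37 ± 0.13 (SE), but the gene did not pass in the fit across all genes (adjusted p = 0.126). An exact two-sided permutation test over the 35 splits of the arrays gave p = 0.0571. The place of its probes relative to the deleted part of the gene is not given in the sources used here, so the remaining signal checks neither the deletion nor the protein.

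Of the 13083 genes, 333 rose and 424 fell in KO cells at an adjusted p under 0.05 (limma). At least a 2-fold change was seen in 143 of the risen and 134 of the fallen genes. In 752 of these 757 genes the 3 KO arrays lay outside the range of the 4 Het arrays on the side of the change. This was so for 19.5% of all tested genes, against 5.71% expected by chance. Among the risen genes the largest changes were in Mrc1, the macrophage mannose receptor (at least 3.90-fold, with all Het arrays below the floor), Csf1r, the macrophage pore-forming gene Mpeg1 (8.09-fold), Pld4 (6.83-fold), the major urinary protein genes Mup19 and Mup13 (at least 1.68-fold and 2.17-fold), the kallikrein Klk1b22 (6.57-fold), the complement genes C6 (6.26-fold) and C1qa (6.19-fold), and the integrin Itgad (at least 2.30-fold). Csf1r was above the floor in 2 of 4 Het arrays, Mpeg1 and C6 in 1 of 4. The order uses the fitted change, which for Mrc1, Mup19, Mup13 and Itgad rests on Het values below the floor. Itga9 (5.56-fold) and Siglech (4.54-fold), above it on all arrays, rose by more than the bounds of these genes. The largest falls were in Il1rl1, the enkephalin precursor Penk (10.4-fold), Tigit, Nav2 (5.59-fold), Itgae, Rgs9 (4.64-fold), the drug transporter Abcb1a (4.28-fold), the decoy receptor Il1r2 (4.18-fold), the chemokine receptor Ccr4 (at least 3.05-fold, with no KO array above the floor) and the carboxylesterase Ces2c (3.96-fold). Il1rl1 was above the floor in 1 of 3 KO arrays, Penk and Tigit in 2 of 3. The order of the falls, Ccr4 among them, thus rests in part on values below the floor. With each array centred on its median the counts were 406 higher and 291 lower. Of the changed genes 58.2% were then higher, against 44.0% in the deposited scaling and 50.5% after quantile normalization. That array median covers all 28846 probe sets, 5222 negative controls among them, which read 4.87 to 5.05 in KO and 4.91 to 5.42 in Het arrays (medians). The median change of the tested genes was 0.046 after centring, 0.020 after quantile normalization and -0.017 in the deposited scaling. Leaving out KO replicate 3 gave 209 higher and 271 lower genes, Het replicate 3 gave 210 and 240, KO replicate 2 gave 238 and 247, and Het replicate 2 gave 225 and 248. Without KO replicate 1, the array with the highest myeloid signal, 241 were higher and 300 lower. The myeloid marker mean as a covariate, added after the data were seen, left 1 higher and 7 lower genes. It shares 83.4% of its variance with genotype, and the median SE grew from 0.14 to 0.33. The lost calls therefore cannot separate myeloid signal from genotype.

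**Figure D1:**
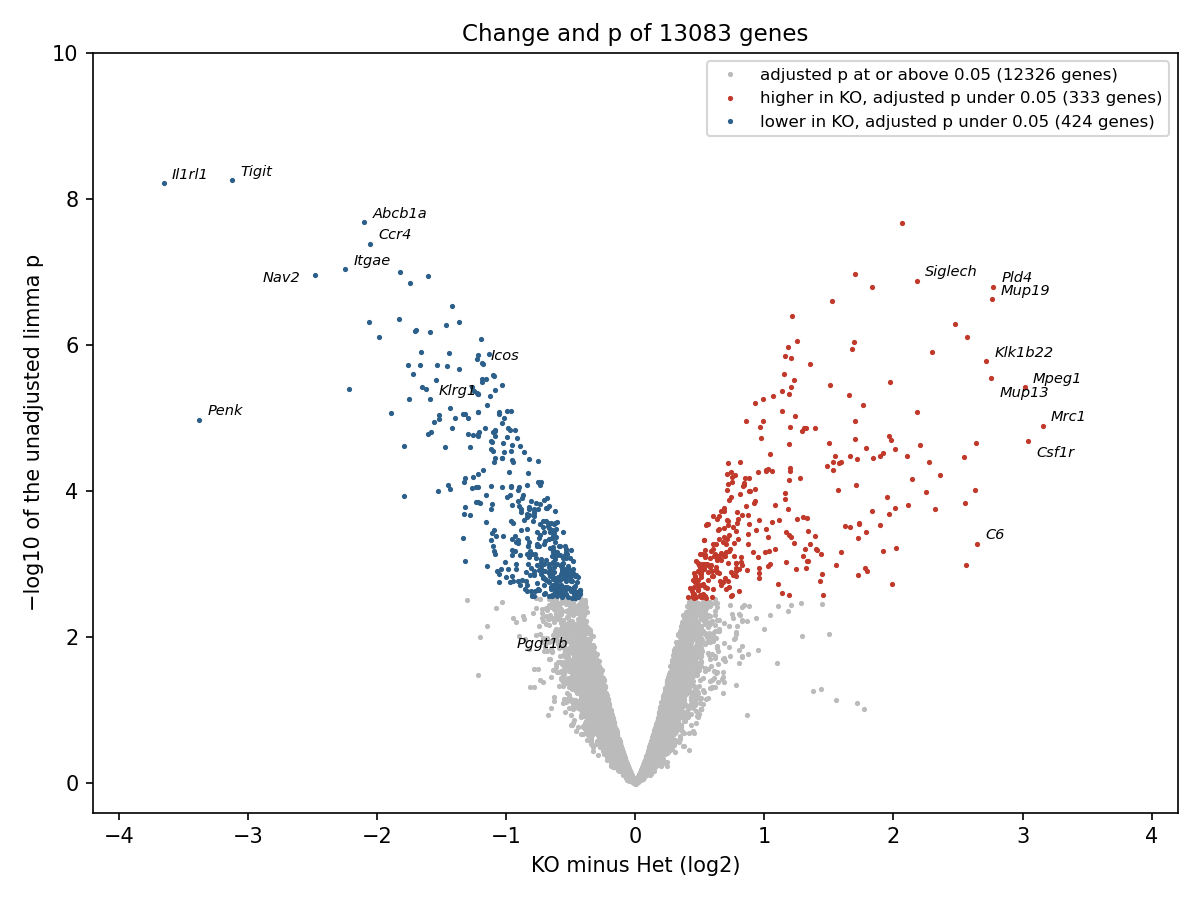
Log2 change (KO minus Het, x axis) and −log10 of the unadjusted limma p (y axis) of the 13083 tested genes; each point is 1 gene, and colours mark the 333 genes that rose and the 424 that fell at an adjusted p under 0.05. Il1rl1, Tigit and Penk lie farthest to the left and Mrc1, Csf1r and Mpeg1 farthest to the right.

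Effector Treg genes had the smallest camera p of the lists at the preset correlation. Of 48 measured members, 30 fell, 1 rose and 17 did not pass, with a median log2 change of -0.79; adjusted over the list alone, 37 fell and 1 rose. Besides Il1rl1 (-3.65 ± 0.22, SE), Tigit (-3.12 ± 0.18) and Itgae, the falls included the costimulatory receptor Icos (-1.18 ± 0.12, adjusted p = 0.00051), Klrg1, a marker of terminally differentiated cells (-1.59 ± 0.19, above the floor in 1 of 3 KO arrays), and the inhibitory receptor Pdcd1 (3.27-fold). The transcription factors Batf (2.12-fold), Nfil3 (3.39-fold), Maf (1.67-fold) and Prdm1 (at least 2.15-fold) also fell, as did granzyme Gzmb (2.95-fold) and Il10, which read 5.81 ± 0.08 in Het and 4.82 ± 0.23 in KO samples (SD, n = 4 and 3; at least 1.15-fold, no KO array above the floor). The inhibitory receptor Ctla4 (-0.80 ± 0.17, adjusted p = 0.0212) and the adhesion receptor Cd44 (-0.64 ± 0.13, adjusted p = 0.0148) fell by less. Irf4 (-0.43 ± 0.14, adjusted p = 0.121) and Nr4a1 (0.33 ± 0.17, adjusted p = 0.331) did not pass. The member that rose was Cd74, the invariant chain of MHC class II (1.39 ± 0.18). Camera with its preset correlation gave the list an adjusted p of 7.51e-24, and with an estimated correlation the adjusted p = 0.0674. Myeloid markers were higher on the same KO arrays, by a median of 1.54, or 0.78 with no filter on dim genes. The Ctla4 call was lost without KO replicate 2 (-0.74), KO replicate 3 (-0.72), Het replicate 2 (-0.78) or Het replicate 3 (-0.68), and the Cd44 call without KO replicate 1 (-0.59) or KO replicate 2 (-0.63).

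**Figure D2:**
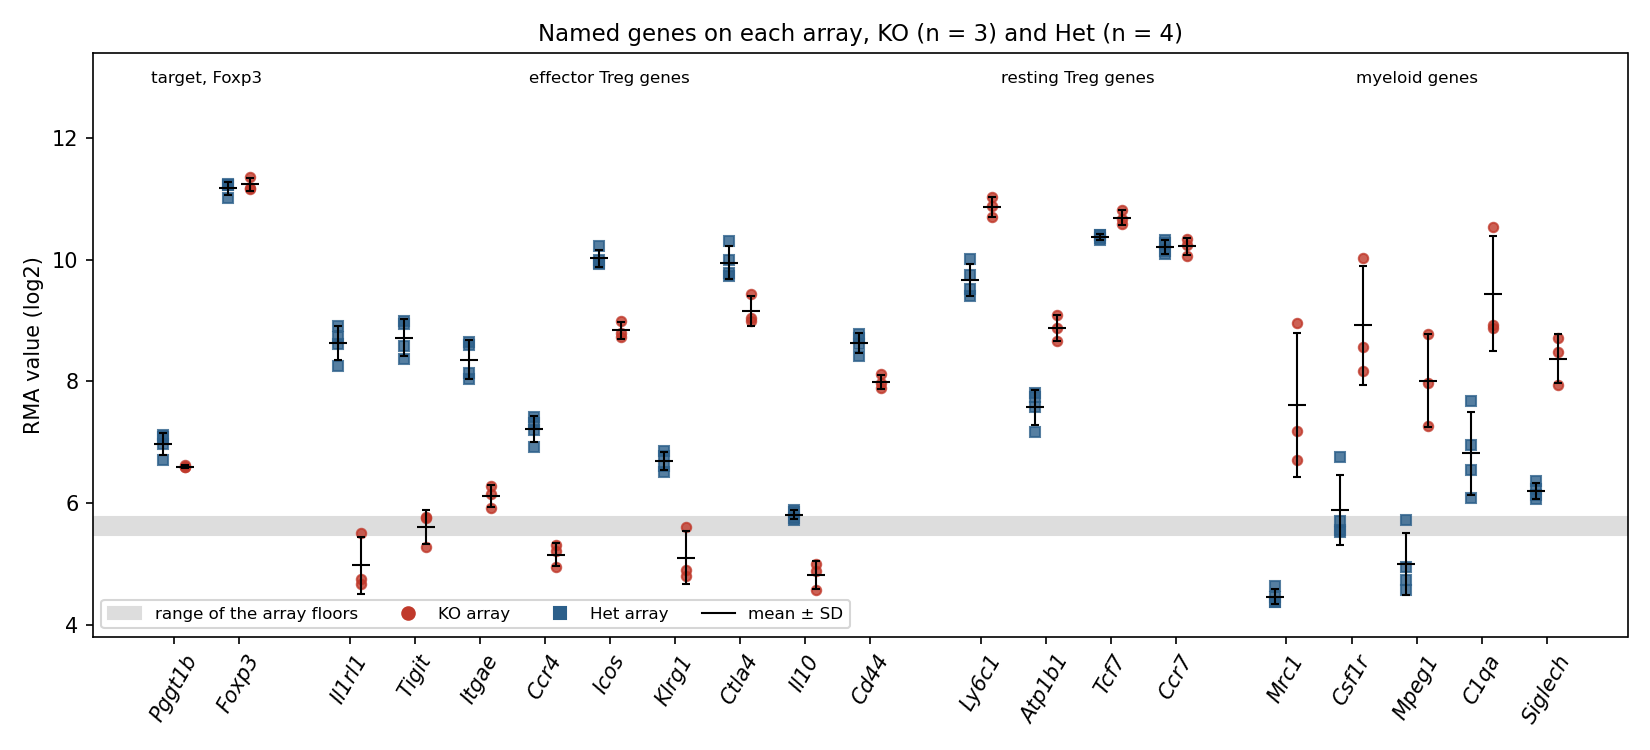
RMA log2 values (y axis) of named genes on each array, with KO arrays (n = 3) as circles, Het arrays (n = 4) as squares and the mean ± SD of each group in black; the grey band spans the array floors, 5.48 to 5.77. The KO arrays lie below all Het arrays for the 9 effector Treg genes and above them for the 5 myeloid genes, while Foxp3 and Ccr7 overlap.

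Core Treg genes, the set that marks Treg against other CD4 T cells, gave 14 falls and no rise among 28 measured members, at a median of -0.55. Adjusted over the list alone, 16 fell and 3 rose. The TGF-beta activating integrin Itgb8 fell 3.36-fold, the ectoenzyme Nt5e, also in the effector list, 2.45-fold, the transcription factor Ikzf2 2.32-fold and the coreceptor Nrp1 1.82-fold. Foxp3 read 11.18 ± 0.11 in Het and 11.24 ± 0.11 in KO samples (SD, n = 4 and 3). The Il2ra probe set was dim, above the floor in 2 of 4 Het and 1 of 3 KO arrays, and differed by -0.16 ± 0.27 (SE). The camera adjusted p was 1.09e-09 with the preset correlation, and the adjusted p = 0.0674 with an estimated correlation. Without members that another list also holds the median was -0.35. Myeloid markers rose by a median of 1.54 on these arrays.

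Resting or central Treg genes rose in 8 of 36 measured members and fell in none, at a median of 0.28; adjusted over the list alone, 15 rose. Ly6c1 rose by 1.20 ± 0.16 (SE) and the sodium pump subunit Atp1b1 by 1.31 ± 0.17, both with an adjusted p of 0.00153. The quiescence factors Klf2 and Klf3 (1.75-fold) and the transcription factors Lef1 (1.52-fold) and Satb1 (1.60-fold) also rose. Tcf7 (0.32 ± 0.11, adjusted p = 0.133) and the lymph node homing receptor Ccr7 (0.01 ± 0.12, adjusted p = 0.982) did not pass. This list had a camera adjusted p of 1.43e-10, and an adjusted p = 0.126 with an estimated correlation. Conventional CD4 T cell markers, of which several are also in the resting list, rose in 4 and fell in 1 of 14 measured members (6 and 3 adjusted over the list alone), at a median of 0.26. The phosphodiesterase Pde3b rose by 1.70 ± 0.23, and the costimulatory receptor Cd226 fell 1.47-fold. As a list they had an adjusted p of 0.0145 with the preset correlation, and the adjusted p = 0.292 with an estimated correlation. Without the members that another list also holds, this list had a median of 0.04 and did not pass. Leaving out KO replicate 3 left 4 resting and 2 conventional genes risen, and KO replicate 2 or Het replicate 3 left 5 resting genes. Conventional genes fell in 2 without KO replicate 3 and in 0 without KO replicate 2 (limma). Both lists moved on arrays where myeloid markers rose by a median of 1.54.

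Chemokine receptors, integrins and homing genes fell in 11 and rose in 3 of 32 measured members (13 and 6 adjusted over the list alone), at a median of -0.24. Beside Ccr4 (at least 3.05-fold) and Itgae (-2.25 ± 0.17, SE), the fall took in Itgb1 (2.57-fold), Itgb8, the follicle homing receptor Cxcr5 (2.43-fold) and the mucosal receptor Ccr6 (2.39-fold). Vcam1 (3.31-fold), Ccr3 (3.77-fold, above the floor in 1 of 4 Het arrays) and Itga6 (1.36-fold) rose. This list had an adjusted p of 0.00327 with the preset correlation, and the adjusted p = 0.113 with an estimated correlation. Without members shared with another list it had a median of -0.18 and did not pass. The median was -0.11 without KO replicate 1 and 0.021 with the myeloid covariate, where camera still called the list lower, and 1 member rose without Het replicate 1 or Het replicate 3. Vcam1, itself in the myeloid marker list, and Ccr3 rose on arrays where myeloid markers rose by a median of 1.54.

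Genes induced by T cell receptor signalling fell in 5 and rose in 1 of 40 measured members, at a median of -0.29; adjusted over the list alone, 17 fell and 1 rose. The transcription factor Bhlhe40 fell by 1.22 ± 0.16 (SE), and Nr4a2 fell 2.07-fold. Myc, a driver of cell growth, rose by 0.55 ± 0.10 (adjusted p = 0.0113). For this list the adjusted p was 0.00228 with the preset correlation, and the adjusted p = 0.292 with an estimated correlation. The number of falls was 2 without KO replicate 1, KO replicate 2, KO replicate 3 or Het replicate 2, 1 without Het replicate 3 and 3 without Het replicate 4. Helper T cell cytokine and lineage genes fell in 6 and rose in 2 of 18 measured members (8 and 3 adjusted over the list alone), with falls in Cxcr5 (-1.28 ± 0.18) and Tnfsf11, the RANK ligand (1.79-fold), and rises in Eomes (0.85 ± 0.13) and the IL-23 receptor Il23r (1.44-fold, above the floor in 1 of 4 Het arrays). Camera gave an adjusted p of 0.0382, and the adjusted p = 0.211 with an estimated correlation. Without KO replicate 1, KO replicate 2 or Het replicate 4 the call was lost, with medians of -0.08, -0.27 and -0.14 against -0.16. It was also lost with array weights (-0.13), with the background level as a covariate (-0.14) and without members that another list also holds (-0.15). Without KO replicate 3 its median was -0.28, after median centring -0.10 and with no filter on dim genes -0.11. The falls numbered 2 without KO replicate 2 and 3 without KO replicate 1, Het replicate 2 or Het replicate 3, and 1 member rose without KO replicate 1, 2 or 3 or Het replicate 1 or 3. Myeloid markers rose by a median of 1.54 on these arrays. With their mean as a covariate the T cell receptor and helper list medians were 0.054 and 0.084, and neither passed. That mean shares 83.4% of its variance with genotype, so these lost calls cannot separate myeloid signal from genotype.

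Apoptosis and survival genes fell in 4 of 34 measured members, as many as adjusted over the list alone, at a median of -0.10. The survival gene Bcl2a1b fell by 0.95 ± 0.14 (SE). The adjusted p was 0.0382 with the preset correlation, and the adjusted p = 0.292 with an estimated correlation. Its call was lost without Het replicate 1 (-0.08), KO replicate 2 (-0.07) or Het replicate 3 (-0.11), and with each array centred on its median (-0.03). Heat shock and dissociation stress genes fell in 6 and rose in 1 of 22 measured members (8 and 1 adjusted over the list alone), at a median of -0.34. The chaperone Hspa1a fell by 1.11 ± 0.22 and the mitochondrial chaperones Hspd1 (1.38-fold) and Hspe1 (1.43-fold) fell by less. The member that rose, the haem-degrading enzyme Hmox1 (1.30 ± 0.28), is also in the myeloid list, and its call was lost without Het replicate 2 (1.22) or Het replicate 3 (1.24). Both lists were measured on arrays where myeloid markers rose by a median of 1.54. The adjusted p of the list was 0.0025, and the adjusted p = 0.292 with an estimated correlation. The falls in it numbered 1 without KO replicate 1, Het replicate 2 or Het replicate 3, 2 without KO replicate 2, and 3 without KO replicate 3 or Het replicate 1. Its median was -0.19 without KO replicate 1 and 0.086 with the myeloid covariate.

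Cytosolic ribosomal protein genes were lower in KO cells for all 52 measured members by sign, of which 6 fell at the threshold and 28 adjusted over the list alone. Rps21 fell by 0.91 ± 0.15 (SE), the largest of these, Rpl34 was 1.56-fold lower and Rps12 fell by 0.54 ± 0.11, against a list median of -0.32. The camera adjusted p was 1.10e-13, and the adjusted p = 0.292 with an estimated correlation. Falls numbered 1 without KO replicate 1, KO replicate 2, Het replicate 2 or Het replicate 3, 2 without KO replicate 3, 3 without Het replicate 1 and 10 without Het replicate 4. The Rps12 call was lost without KO replicate 1 (-0.53), KO replicate 2 (-0.52), KO replicate 3 (-0.57), Het replicate 2 (-0.55) or Het replicate 3 (-0.53). Oxidative phosphorylation genes had a median of -0.20 over 47 measured members, of which 43 were lower by sign and 2, Atp5c1 (-0.72 ± 0.16) and Ndufa4 (-0.67 ± 0.17), fell at the threshold; adjusted over the list alone, 0 passed, against 2 over all genes. Camera gave them an adjusted p of 2.41e-05, and the adjusted p = 0.542 with an estimated correlation; fry did not call them (adjusted p = 0.164), nor did the exact permutation test (p = 0.0857). Without Het replicate 4, 4 members fell, and without Het replicate 1 the median was -0.13. Leaving out 1 array ended the call of Atp5c1 in 5 of 7 cases, all but KO replicate 2 and Het replicate 4, and that of Ndufa4 in 6 of 7, all but Het replicate 4, with changes of -0.61 to -0.73 and -0.54 to -0.75. Myeloid markers were higher by a median of 1.54 on the same KO arrays.

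Cholesterol and mevalonate synthesis genes, the pathway that supplies the geranylgeranyl lipid, rose in 2 of 27 measured members, as many as adjusted over the list alone, at a median of 0.18. The list had an adjusted p of 0.00224 with the preset correlation, and the adjusted p = 0.292 with an estimated correlation. Without KO replicates 1 or 2 or Het replicates 1, 2 or 3, 1 member rose, and without KO replicate 1, 1 fell. Myeloid markers had a median change of 1.54 on these arrays, and with their mean as a covariate 0 members rose (limma) and the list, at a median of 0.15, did not pass. That mean shares 83.4% of its variance with genotype and left 1 higher gene among all 13083. These lost calls therefore cannot separate myeloid signal from genotype. Prenylation enzymes fell in 2 of 14 measured members (4 adjusted over the list alone) and did not pass as a list (adjusted p = 0.404). These were Rabggtb, a subunit of Rab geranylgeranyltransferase (-0.69 ± 0.12, SE), and its escort protein Chm (-0.60 ± 0.15), whose call was lost without any 1 array except KO replicate 3, at -0.43 to -0.63. The farnesyltransferase subunit Fntb differed by 0.35 ± 0.15 (adjusted p = 0.224).

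Cell cycle genes did not pass as a list (median -0.15, adjusted p = 0.0873) but did in 5 of 15 other settings: without KO replicate 1 (-0.16) or Het replicate 4 (-0.17), with no filter on dim genes (-0.16), with array weights (-0.15) and with the background level as a covariate (-0.17). Without Het replicate 4, 3 members fell. The median was -0.084 after median centring and -0.083 after quantile normalization. Of 36 measured members 2 fell, as many as adjusted over the list alone: the proliferation marker Mki67 (-0.84 ± 0.20, SE) and thymidylate synthase Tyms (-0.77 ± 0.17). Mki67 lost its call without KO replicates 2 or 3 or Het replicates 1, 2 or 3 (-0.67 to -0.82), and Tyms without KO replicates 1 or 2 or Het replicates 1, 2 or 3 (-0.67 to -0.76). Interferon response genes had 1 fall among 33 measured members, Oas1a (-0.51 ± 0.12), 1 also adjusted over the list alone, and an adjusted p of 0.528; the Oas1a call was lost without any 1 array except Het replicate 4, at -0.47 to -0.54. Glycolysis genes (24 measured, median -0.07, adjusted p = 0.793) and mTORC1 and amino acid response genes (25 measured, median 0.02, adjusted p = 0.336) had no member that passed, nor 1 adjusted over the list alone. Pfkp (-0.30 ± 0.11) and Gars (0.33 ± 0.10) had the smallest p in these lists.

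**Figure D3:**
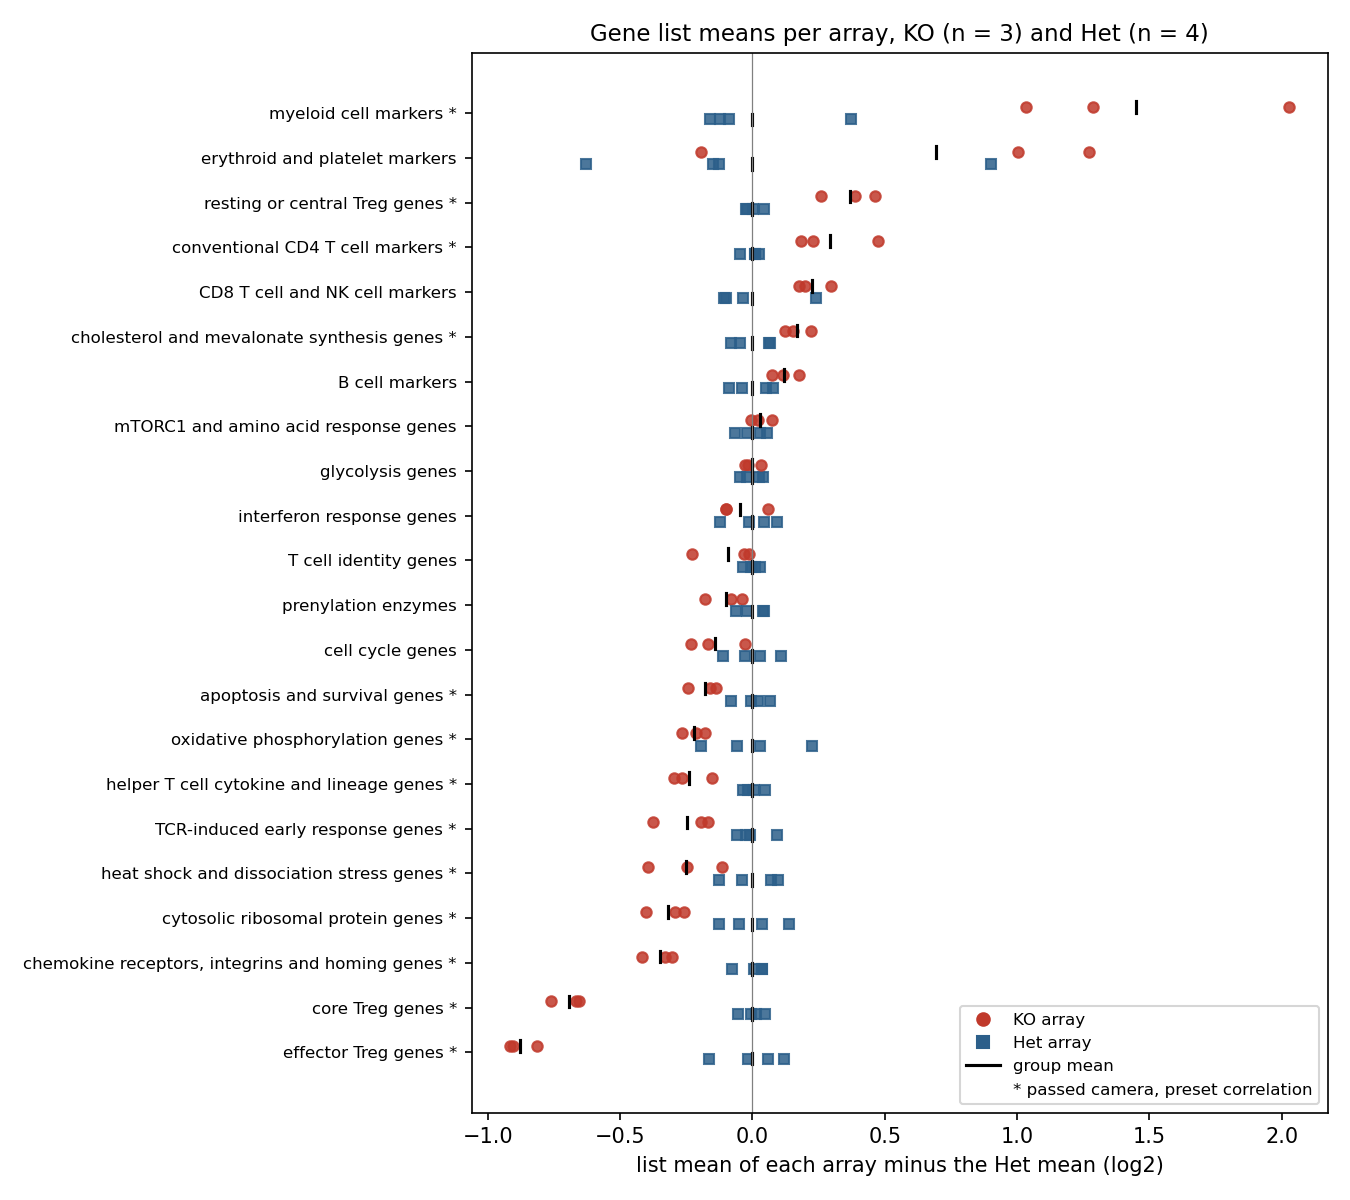
Mean of each tested gene list in the text on each array minus the mean of the 4 Het arrays (x axis, log2), with KO arrays as circles, Het arrays as squares, group means as black bars, and asterisks at the lists that passed camera with its preset correlation. The effector and core Treg lists lie lowest, the myeloid markers highest, and KO replicate 1 has the highest myeloid mean.

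Markers of other cells that the sort could hold were measured on the same arrays. Myeloid markers rose in 16 of 21 measured members and fell in none, at a median of 1.54 (18 adjusted over the list alone). Of the 21, 13 were above the floor on all Het arrays, and the filter could be met through the 3 KO arrays alone. With no filter on dim genes the median was 0.78. The DAP12 adaptor Tyrobp rose 3.39-fold, the plasmacytoid dendritic cell lectin Siglech 4.54-fold, the transcription factor Spi1 4.04-fold and Cd68 2.90-fold. Lysozyme Lyz2 (0.83 ± 0.30, SE, adjusted p = 0.146), Cst3 (0.08 ± 0.13) and Ctss (-0.11 ± 0.12) did not pass. Per array the list mean was 8.42, 7.43 and 7.69 in KO samples 1 to 3 and 6.24 to 6.77 in Het samples. Their adjusted p was 1.64e-18 with the preset correlation, and the adjusted p = 0.163 with an estimated correlation. Without KO replicate 1 the myeloid median was 1.17 with 14 members risen, while 26 effector Treg genes fell at a median of -0.79 and 7 resting Treg genes rose at a median of 0.33.

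B cell markers rose in 2 of 10 measured members, Ly6d (1.08 ± 0.19, SE) and Blnk (0.70 ± 0.17), with a median of 0.06 and an adjusted p of 0.424, although the list passed with no filter on dim genes (0.12) and its median was -0.038 without KO replicate 3, 0.039 without Het replicate 3, 0.088 without KO replicate 2 (where 1 member fell) and 0.094 without Het replicate 4; adjusted over the list alone, 2 rose and 1 fell. The Blnk call was lost on leaving out any 1 array except Het replicate 4, at 0.50 to 0.81. CD8 T cell and NK cell markers rose in 2 and fell in 1 of 5 measured members (3 and 1 adjusted over the list alone), with rises in Eomes and Cd8b1 (1.57-fold) and a fall in the granule gene Nkg7 (-1.10 ± 0.12), and did not pass as a list (adjusted p = 0.0666) except without Het replicate 1 (median 0.48 against 0.40) or with no filter on dim genes (0.16), and 1 member rose without KO replicate 2 or KO replicate 3. Erythroid and platelet markers had no passing member among 9, also adjusted over the list alone, and an adjusted p of 0.0852, but differed widely between arrays of 1 genotype. Haemoglobin gene Hba-a1 read 10.38, 9.71 and 7.49 in the KO samples and 6.91 to 9.17 in the Het samples. That list passed without KO replicate 3 (median 0.32, 2 members risen) or Het replicate 4 (0.31) against a median of 0.15, which was 0.060 with no filter on dim genes. Only Derl3 of the plasma cell markers was above the floor (-0.34 ± 0.15, adjusted p = 0.242), so that list was not tested. T cell identity genes had no passing member among 19, also adjusted over the list alone, at a median of -0.07 and an adjusted p of 0.248, and 1 fell without KO replicate 3. Cd28 (-0.58 ± 0.16, adjusted p = 0.0608) and Cd3d (-0.40 ± 0.12, adjusted p = 0.0768) had the smallest p in it.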

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

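Among the tests in this part, the splits of the myeloid mean, the comparison with B cell markers and the myeloid covariate were chosen only after the rise of the myeloid genes had been seen. In 97 groups of 4 Het values (named genes and list means), 5 had 1 array far from the other 3, where chance gives 4.85. Csf1r read 6.75 in Het replicate 1 against 5.52 to 5.71 in the others, a gap of 0.846 of the whole range. The mean of the myeloid markers was 6.77 in the same array against 6.24 to 6.31 (0.867 of the range). Foxp3 read 11.01 in it against 11.22 to 11.24 (0.930). In Het replicate 4, Atp5c1 read 6.71 against 7.24 to 7.26 (0.967), and Blnk 6.41 against at most 6.05 (0.863).

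Myeloid genes were higher in KO samples, by a list mean difference of 1.45. Of the 35 splits 1, the real one, gave so large a difference and the highest other reached 1.31, but the KO and Het means had been seen not to overlap when this was chosen, so it does not exclude chance. A general loss of sort purity, with every other cell type rising alike, is argued against by the B cell markers. Their median was 0.059 (0.12, and called higher, with no filter on dim genes), and the 3 neutrophil genes above the floor were at 0.13. The exact two-sided permutation p of the difference of the myeloid from the B cell mean was 0.0286, the smallest the splits allow. It adds no support, since the myeloid means had been seen not to overlap. CD8 T and NK cell markers were at 0.40, and erythroid and platelet markers at a median of 0.15 and a mean of 0.69. Entry of some other cell types is thus not excluded. Myeloid cells that passed the CD4+ YFP+ gate stay open. Macrophage genes not examined before had a median of 0.72 against 1.54 for the markers, between the bounds set for and against this explanation. Over all members, dim ones included, the medians were 0.64 against 0.78, which meets the bound for it. Cst3 (0.08) and Ctss (-0.11) did not pass. At 10.44 and 9.36 in Het samples, a few such cells could hardly raise them, so they do not decide it. Lyz2 (0.83) was higher without passing. A change of these genes within Treg cells by genotype is also open and untested, and of the 21 markers 13 were above the floor on all Het arrays and 2 are in another list.

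With the myeloid mean as a covariate, 1 gene rose (Acvr1c, with no Het array above the floor) and 7 fell: Il1rl1 (-4.69), Tigit (-3.84), Spaca1 (-2.70), Klrg1 (-2.58), Slc43a3 (-2.50), Ggh (-2.45) and Cyp4f18 (-2.38). Without it Spaca1 (-0.46, adjusted p = 0.490) and Ggh (-0.86, adjusted p = 0.0748) had not passed. This mean shares 83.4% of its variance with genotype, and the median SE of a gene grew from 0.14 to 0.33, while the changes of the 757 genes had a median ratio of 0.896 to those without it. Those SEs are medians over all tested genes, and in the median ratio moves up and down cancel, so it does not show how far single changes moved. For 698 of the 757 the sign was as before. The effector and resting Treg lists had medians of -0.95 and 0.53 with it. Acvr1c, Spaca1, Slc43a3, Ggh and Cyp4f18 were named after their values were seen.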

How the results depend on the processing

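The myeloid covariate among these tests was chosen only after the data had been seen. Of the 757 genes, the other settings kept the sign of all that they tested, and shared from 441 (without KO replicate 3) to 754 (mean of probe sets) calls with the deposited scaling. Of 53 named genes that passed, 12 lost the call under at least 1 of these settings, and 8 of the other 20 gained it. Over all settings, list calls were the same in 378 cases, lost in 42, gained in 12 and reversed in camera's direction in 5, and named genes the same in 1014, lost in 118, gained in 13 and reversed in 16. Pggt1b stayed between -0.46 and -0.31 with an adjusted p of 0.0835 to 0.275.

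Array weights gave 547 higher and 697 lower genes, and an adjusted p under 0.10 gave 564 and 679, the latter by its construction. Leaving out 1 array gave 209 to 290 higher and 240 to 455 lower genes, with fewer samples in each fit. Camera with an estimated correlation and the exact test of the list mean each called 0 lists higher and 0 lower, against 4 and 9, with 5 and 10 lists at an unadjusted p under 0.05. With the myeloid covariate 1 gene was higher and 7 lower, and 1 list was higher. Foxp3 ranged from -0.0011 (without KO replicate 2) to 0.099 (without KO replicate 1), Il2ra from -0.44 to 0.19 and Ccr7 from -0.051 to 0.086 over the left-out arrays, and the interferon list median from -0.14 to 0.034, with camera's direction turned without KO replicate 2 (-0.045). Among these, Ccr7 was also negative without Het replicate 2 (-0.03), KO replicate 3 (-0.0054) and Het replicate 3 (-0.012), and with quantile normalization (-0.014). Il2ra was 0.085 with array weights. The myeloid covariate reversed the sign of C6 (-0.81), C1qa (-0.19), Hspa1a (0.088), Hmox1 (-0.48), Derl3 (0.21), Cd28 (0.18), Il2ra (0.95), Fntb (-0.15), and camera's direction for heat shock genes (median 0.086), B cell markers (-0.12), myeloid markers (-0.0070, by construction) and T cell identity genes (0.045). It also turned the medians of the T cell receptor (0.054), homing (0.021) and helper T cell lists (0.084), for which camera's direction did not turn. For the others the cause was not tested. A comparison of both deposited tables was not run as a setting, since 0 values differ between them. The 8819 genes left out, 92 list members among them, lie near the array background, where a fall cannot be followed further.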

Other observations

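The gene families in this paragraph and the next were chosen after their values were seen, as were the tests on T cell identity genes and on the resting list used below. The gene ontology terms and the added cell type lists were chosen after the myeloid rise was seen, but before their own values were. MHC class II genes, which present antigen to CD4 T cells, rose in 5 of 9 measured members at a median of 1.27: H2-Eb1 by 1.70, H2-DMb1 by 1.68, H2-Ab1 by 1.66, H2-DMb2 by 1.53 and H2-Aa by 1.27. Among 1621 gene ontology terms, camera with its preset correlation called 13 higher and 2 lower, the first being antigen presentation through MHC class II (8 of 13 genes rose, adjusted p = 1.12e-08, and adjusted p = 0.982 with an estimated correlation). With an estimated correlation camera called 0 terms, with 50 at an unadjusted p under 0.05. Myeloid markers rose by a median of 1.54 on these arrays. Of the added lists, macrophage genes rose in 4 of 10 members above the floor (Lgmn 1.32, Apoe 0.88, and Tgfbi and Epb41l3, near the floor in Het samples) and conventional dendritic cell genes in 2 of 8 (Cd209a 1.59, Wdfy4 0.74, list median 0.21). Among macrophage genes that the filter left out, Aif1 (2.32), Spic (1.81), Clec4n (1.76), Cd5l (1.59) and Pparg (1.22) were higher, each highest in KO replicate 1. Msr1 (-0.037), Folr2 (0.0086) and Cd36 (0.0013), also left out, were flat. Plasmacytoid dendritic cell genes not examined before fell in 2 of 7, at a median of -0.25, but had a median of 0.11 over all 12 members on the array. Neutrophil genes (3 above the floor, median 0.13) and liver genes (6, median 0.12) had no member that passed, and no salivary gland gene of 17 was above the floor on at least 3 arrays (median of all 0.074). Over all members on the array, dim ones included, the medians were 0.64 for macrophage, 0.27 for conventional dendritic cell, 0.14 for liver and -0.0090 for neutrophil genes.

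Major urinary protein genes, which encode carriers made mainly in liver, rose in the 4 members that passed the filter, of 13 on the array: Mup1 3.78-fold, with 1 of 4 Het arrays above the floor, and Mup19, Mup13 and Mup2 at least 1.68-fold, 2.17-fold and 2.78-fold, with none, so that these 3 passed it through the KO arrays. Albumin (Alb), the main liver plasma protein and not in the liver list, rose at least 2.37-fold, with no Het array above the floor. The kallikreins Klk1b22 (2.72) and Klk1 (1.73) rose among 3 measured. Myeloid markers rose by a median of 1.54 on these arrays. KO replicate 1 had the highest value of the KO samples for Mup19 (7.09), Alb (7.55), Hba-a1 (10.38) and the myeloid mean (8.42). Whether the probes of such close paralogs share targets was not tested. Beta-tubulin genes rose in 2 of 8 members, Tubb2b (1.83) and Tubb2a (1.26), at a median of 0.32, and alpha-tubulin genes in 0 of 7 by limma, at a median of 0.24. Histone genes fell in 14 of 60 measured members, at a median of -0.37, or -0.31 after median centring. Some of these share identical values on all arrays, leaving 56 distinct profiles (14 lower, median -0.39). Whether the probes of the remaining histone genes share targets was not tested, so these may not be separate measurements. Both multidrug transporter genes fell, Abcb1a (-2.10) and Abcb1b (-1.44). The signs of these families were the same under median centring and quantile normalization.

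Over all genes, 1 of 35 splits, the real one, called 757 genes, against 2 in the highest other. This counts all genes, not the effector genes. In splits that mix the genotypes their difference adds to the spread, which lowers the count. Chance is thus not excluded by it for the effector fall. The exact permutation test of the effector list mean gave p = 0.0286, the smallest the splits allow, and an adjusted p of 0.0657. For the list calls the real split ranked 1 of 35, with 13 called against 11 in the highest other (Het replicates 1, 2 and 3 as the group of 3) and 10 in 5 more. That rank does not exclude chance. Camera with an estimated correlation and the adjusted exact test called 0, with 5 and 10 lists at an unadjusted p under 0.05. Dilution by cells other than T cells is argued against by the medians, -0.074 for T cell identity genes against -0.79. The exact two-sided permutation p of the difference was 0.0286, the smallest the splits allow. It adds no support, since the test was chosen after these values had been seen. On KO replicate 1 the T cell identity mean was lower, 10.415 against 10.61 to 10.67 on the other arrays. With the olfactory background level as a covariate the effector median was -0.81. That level overlapped between the genotypes (3.73 to 3.84 in KO and 3.76 to 3.88 in Het arrays), so the covariate could hardly move the change. Positive control probe sets read 8.82 to 8.92 in KO and 8.67 to 8.77 in Het arrays. A difference in signal range between the genotypes was therefore not tested. A smaller share of effector cells among the sorted cells may underlie the effector fall, as resting genes rose by a median of 0.28, and lower expression per cell is also open and untested.

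Ribosomal protein and oxidative phosphorylation genes were lower, at medians of -0.32 and -0.20. Other genes of like brightness fell less: both medians lay at percentile 0 of 10000 lists matched on mean expression, whose lowest medians were -0.18 and -0.19. This argues against scaling by brightness alone. The matched genes were drawn independently, so the percentile does not allow for list members that move together between arrays. Oxidative phosphorylation means overlapped, at 9.48 to 9.57 in KO and 9.56 to 9.97 in Het arrays. Ribosomal means did not, at 11.09 to 11.24 and 11.37 to 11.63. A bias against short transcripts cannot be told apart from a change by genotype: 257 other bright genes with a short genomic span had a median of -0.10 and 4342 longer genes 0.02, between the bounds set for and against it. RNA quality per sample is not given in the sources used here.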
